A study of Danio rerio with 4 samples.

How the data were processed

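Total RNA of whole zebrafish embryos was extracted with Trizol and labelled with Cy3 by Roche NimbleGen, per the labels. The 4 arrays were grouped by the genotype in their labels: 2 transgenic and 2 wild type, both heat shocked. The authors deposited a table of 37176 array features with expression values for each array, which were taken as log2 values. The log base was inferred from the highest values, which lie at the log2 limit of a scanner of 16 bits. The scanner, the probe summarisation, the background correction and the normalization are not given in the sources used here. The values carry no detection call, slide or scan date, so signal near the bottom of the range cannot be told from background and batches could not be tested. The authors also deposited their own comparison as a mean log2 fold change and a q-value per feature, per the file headers; the test behind the q-values is not given in the sources used here. The deposited fold change equals the difference of the group means of the 4 arrays within 2.8e-08. A companion copy of that table differed from it only in the printed digits of 7 features and was not used.

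Features were named from the gene symbols in the authors' deposited table, updated through a RefSeq gene table of the assembly GRCz12tu, which was used only for names and for which genes neighbour each other. Of 3055 features with a RefSeq mRNA accession, 2663 matched. A name was taken by accession for 2682 features, by current symbol for 4969, by synonym for 5753, by gene number for 1979 and by clone name for 18, and 4362 kept the symbol of the file. The remaining 17413 features had no symbol, of which 11883 had a human ortholog name. Where 3439 genes had more than 1 feature, the feature with the highest mean over the 4 arrays stood for the gene. Names made of LOC and a number (1278 genes) were not taken as gene symbols when genes were chosen to be named.

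The fold change, transgenic minus wild type, was estimated per feature with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on the values as deposited, with 2 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over all features. The threshold was an adjusted p of 0.05, with a further count at 2-fold. The 35 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, on 1 feature per gene, with Benjamini-Hochberg over the lists. Beside it stand camera with an estimated correlation, fry, and the members past the threshold over all features and adjusted over the list alone. The lists covered ERK feedback, immediate early genes, growth factors, RAS genes, heat shock, p53 targets, senescence and arrest, replication, mitosis, matrix remodelling, inflammation, leukocytes, erythroid, endothelial, skeletal muscle, heart, neuronal, neural progenitor, lens, pigment and neural crest, epidermis, notochord and hatching gland, endoderm and liver, Wnt, Notch, Hedgehog, BMP and TGF-beta, retinoic acid, glycolysis, ribosome biogenesis, ribosomal proteins, unfolded protein response, oxidative stress, apoptosis and clock genes. The lists, the tests and the alternatives were fixed before the data were examined, except for lists extended through human ortholog names. The rule for named genes was fixed then too: the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with both transgenic arrays on the same side of both wild-type arrays, up to 4 members with the smallest p of each list, the RAS genes and hsp70l, and every ERK feedback or immediate early gene past the threshold.

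The limma step was tested on simulated data with 37176 features and 2 arrays per genotype, with 200 changed features in each of 10 runs. It recovered 0.6% of features changed by 1 on the log2 scale, 64.6% of those changed by 2, 89% of those changed by 3 and 96% of those changed by 4. There were 0 calls of wrong sign, and 64 false calls beside 1251 recovered features. In the data far more features passed (6538), which makes the Benjamini-Hochberg cut less strict. The simulated shares are therefore not the shares recovered or falsely called in the data. In simulated lists shifted by 0.7, camera with the preset correlation called 50 of 50 shifted lists with 5 false calls, fry called 42, and camera with an estimated correlation called 0. The simulated features were independent of each other. These counts therefore do not show how the preset correlation fares in lists whose genes are correlated.

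The alternatives were quantile normalization, median centring of each array, leaving out features below the 25th percentile or below the median of mean expression, eBayes with a trend or a robust prior, log2(value + 50), the mean of all features of a gene, the replicate number as a block, an adjusted p of 0.10, the deposited q-values, genes with a symbol in place of features, and leaving out each array in turn. With an array left out, the lone array of its genotype is assumed to vary like the other group. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.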

Results

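RNA of whole zebrafish embryos was measured on 4 arrays labelled with Cy3 alone. The arrays fell into 2 groups of 2: embryos carrying a mutant human HRAS gene under the heat-inducible hsp70 promoter, called transgenic here, and wild-type embryos. The sample titles tag the transgenic arrays ras and the wild-type arrays ab. Neither tag tells whether the genotypes shared genetic background, clutch or handling. Differences in these cannot be told apart from an effect of the transgene for any gene reported here. Per the labels, both genotypes were heat shocked at 37 °C for 1 h at 24 hours post fertilisation, returned to 28.5 °C and collected at 30 hours. The design text gives pools of 50 embryos per array and 3 biological replicates, but only 2 arrays per genotype were given, and all 4 were analysed. Each array held log2 expression values for 37176 features, of which 19763 carried the symbols of 14296 genes. Array medians were 9.62 and 9.61 (log2) for the transgenic arrays and 9.5 and 9.55 for the wild-type arrays. Across features, Pearson's r was 0.996 between the transgenic arrays, 0.988 between the wild-type arrays and 0.966 to 0.973 between genotypes; features are not independent replicates. Precision was limited by the number of arrays. The p-values and SEs do not measure the spread between these pools alone. In eBayes the spread of each feature is drawn toward that of all features, with 2.92 prior beside 2 residual degrees of freedom.

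The comparison asked how the transcriptome of heat-shocked transgenic embryos differed from that of heat-shocked wild-type embryos. Among genes with a symbol, the transgenic embryos had higher levels of cgasa, a homologue of the cytosolic DNA sensor cGAS, which rose by 5.47 ± 0.24 (log2 fold change ± SE, n = 2 arrays per genotype), and of il11b, an interleukin-11 gene, which rose by 5.27 ± 0.18. They also had higher ptgs2b, which encodes a cyclooxygenase-2 (4.31 ± 0.14, 19.9-fold), and higher mmp9, a gelatinase that cleaves extracellular matrix (4.13 ± 0.16, 17.5-fold). The keratin gene krt99 fell by 3.28 ± 0.14 and the forkhead factor gene foxq1b was also lower (-3.03 ± 0.15), while hsp70.3, an inducible chaperone gene, fell by 2.76 ± 0.23 (6.79-fold). By the rule that chose these genes, both transgenic arrays lay on the same side of both wild-type arrays. In all, 6538 of 37176 features passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 3830 higher and 2708 lower in the transgenic embryos, and 3809 of them differed at least 2-fold, 2578 higher and 1231 lower.

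The other genes among the 10 with the largest rises were socs3a, a feedback inhibitor of cytokine signalling (3.83 ± 0.15), sbno2b (3.79 ± 0.26), junba, an AP-1 subunit gene (3.65 ± 0.19), fosl1a, another AP-1 subunit gene (3.56 ± 0.39), fstl3, which encodes an activin-binding protein (3.44 ± 0.17), and si:dkey-73n10.5, for which the authors' deposited table gives the human ortholog TGM2 (3.26 ± 0.15). Their adjusted p values lay between 0.0068 and 0.012 in limma. The mean level of cgasa was 11.69 (SD 0.0176, n = 2) in the transgenic arrays against 6.22 (SD 0.452) in the wild-type arrays, and that of il11b was 10.21 (SD 0.193) against 4.95 (SD 0.155). On the falling side stood hsp70 (-2.69 ± 0.28), the dynein light chain gene dynll2a (-2.51 ± 0.24), nceh1a, which encodes a cholesterol ester hydrolase (-2.46 ± 0.32), a gene known by a clone name (-2.45 ± 0.19), cyp11a1.1, a cholesterol side-chain cleavage enzyme gene (-2.40 ± 0.21), c1ql4l (-2.39 ± 0.28) and the yolk precursor gene vtg7 (-2.24 ± 0.17). All 4 features of cyp11a1.1 and both features of vtg7 fell. The values of hsp70.3, hsp70, cyp11a1.1 and vtg7 are uncertain as to which copy they measure, because near-identical copies exist and the name hsp70 in the file fits more than 1 of them. Of the 20 genes with the largest changes, 9 had a group mean below the lowest 25th percentile of the arrays (7.05): cgasa, il11b and fstl3 in the wild-type arrays, and krt99, foxq1b, nceh1a, c1ql4l, vtg7 and the gene with a clone name in the transgenic arrays. Among genes named below, this holds for fosaa, egr2a, il11a, il1b, csf1ra, cdkn1a, igfbp5a, mmp11a, mpeg1.1, hbae5, hbaa1, gjd6, foxe3, trpm1a, ahsg2 and prss1. An unknown share of signal that low is background, so the true size of these changes is uncertain.

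**Figure D1:**
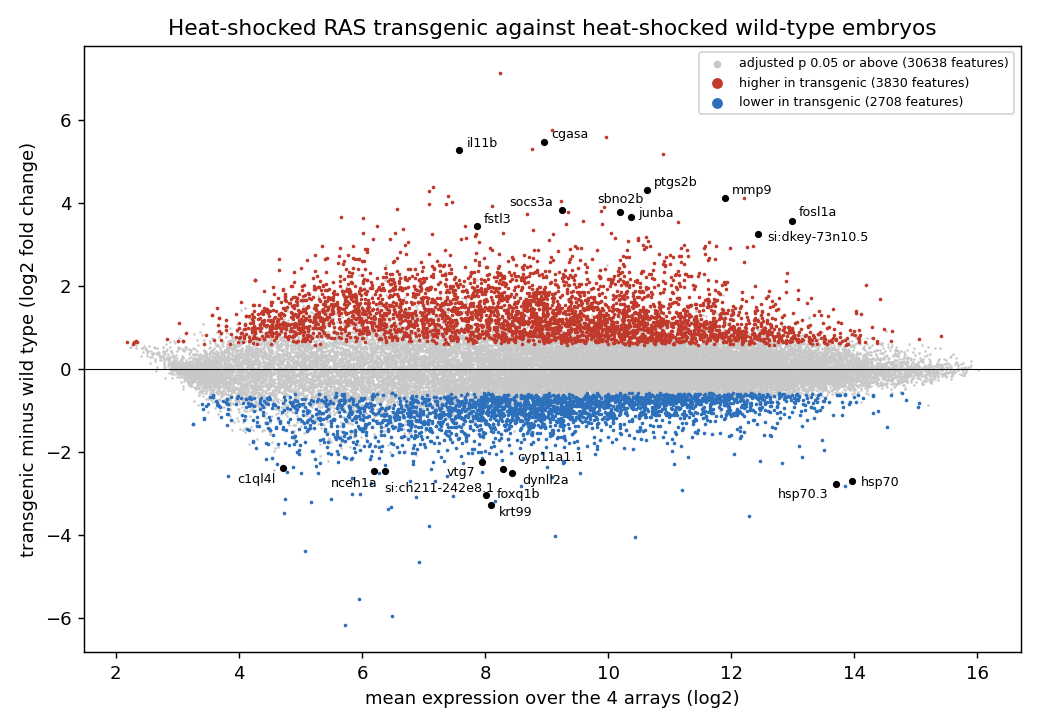
Log2 fold change, transgenic minus wild type, against mean log2 expression over the 4 arrays, with a point per feature. Red points are the 3830 features higher and blue points the 2708 features lower in the transgenic embryos past an adjusted p of 0.05 (limma), grey points the others, and black points the 20 genes with a symbol that rose or fell most, from cgasa (5.47) to krt99 (-3.28).

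The zebrafish RAS genes were looked at as a check of the labels. The level of hrasb was 12.09 in the transgenic and 12.01 in the wild-type arrays (0.08 ± 0.14, adjusted p = 0.71), a difference that turned to -0.01 when each array was centred on its median, and kras differed by 0.25 ± 0.18 (adjusted p = 0.35). No feature was matched to hrasa, nras or hsp70l by zebrafish symbol, and a feature with the human ortholog name NRAS differed by 0.30 ± 0.14 (adjusted p = 0.18). No feature was identified as a probe of the human transgene, so these values check nothing about it. Of 11 RAS family and pathway kinase genes measured by their brightest feature, 0 were higher, and raf1a, which encodes a kinase activated by RAS, was lower (-0.61 ± 0.14, adjusted p = 0.045), while map2k1 differed by 0.48 ± 0.14 without passing (adjusted p = 0.076). The 2 features of rras disagreed: the brighter, which stands for the gene, differed by 0.29 (adjusted p = 0.22), and the other passed upward (0.96). Of the 11, 0 passed adjusted over the list alone, and the list did not shift as a set (camera adjusted p = 0.944).

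Feedback inhibitors and ETS factors of the ERK pathway, which are induced by ERK signalling, rose in part. Of 12 measured, 6 rose, 0 fell and 6 did not pass. The risen genes were the MAP kinase phosphatase genes dusp5 (2.17 ± 0.14, 4.51-fold), dusp4 (1.06 ± 0.19) and dusp6 (0.77 ± 0.18), the ERK inhibitor genes spred2b (1.93 ± 0.23) and spred2a (1.42 ± 0.32), and the ETS factor gene etv4 (1.40 ± 0.14). The counts were 9 higher and 1 lower adjusted over the list alone. The list shifted upward, with a median of 1.01 (camera adjusted p = 0.00684; adjusted p = 0.792 with an estimated correlation). The call of dusp6 (adjusted p = 0.047) ended when arrays were centred on their medians (0.68, adjusted p = 0.055).

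Immediate early transcription factor genes, which respond to growth signals and stress before new protein is made, had the lowest camera p of the 35 lists. Of 14 measured, 9 rose, 0 fell and 5 did not pass; adjusted over the list alone, 10 rose. Besides junba and fosl1a, the rises were in fosab (2.96 ± 0.42) and fosaa (2.15 ± 0.23), which encode FOS subunits of AP-1, in the EGR factor genes egr3 (2.86 ± 0.15) and egr2a (2.78 ± 0.22), in atf3, a stress-induced factor gene (2.30 ± 0.23), and by 0.77 each in klf2a (SE 0.14) and ier5l (SE 0.15). The median was 1.46 (camera adjusted p = 9.36e-05; adjusted p = 0.792 with an estimated correlation). The 3 features of egr2a disagreed, with log2 fold changes from 0.04 to 2.78 and 1 of them past the threshold, whereas both features of fosab and both of fosl1a rose. In the neighbouring list of growth factors, 2 of 13 rose, il11b and its paralog il11a (2.78 ± 0.36), and fgf8a, a fibroblast growth factor gene of embryonic signalling centres, fell by 1.29 ± 0.15; adjusted over the list alone, 2 were higher and 2 lower (camera adjusted p = 0.877).

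**Figure D2:**
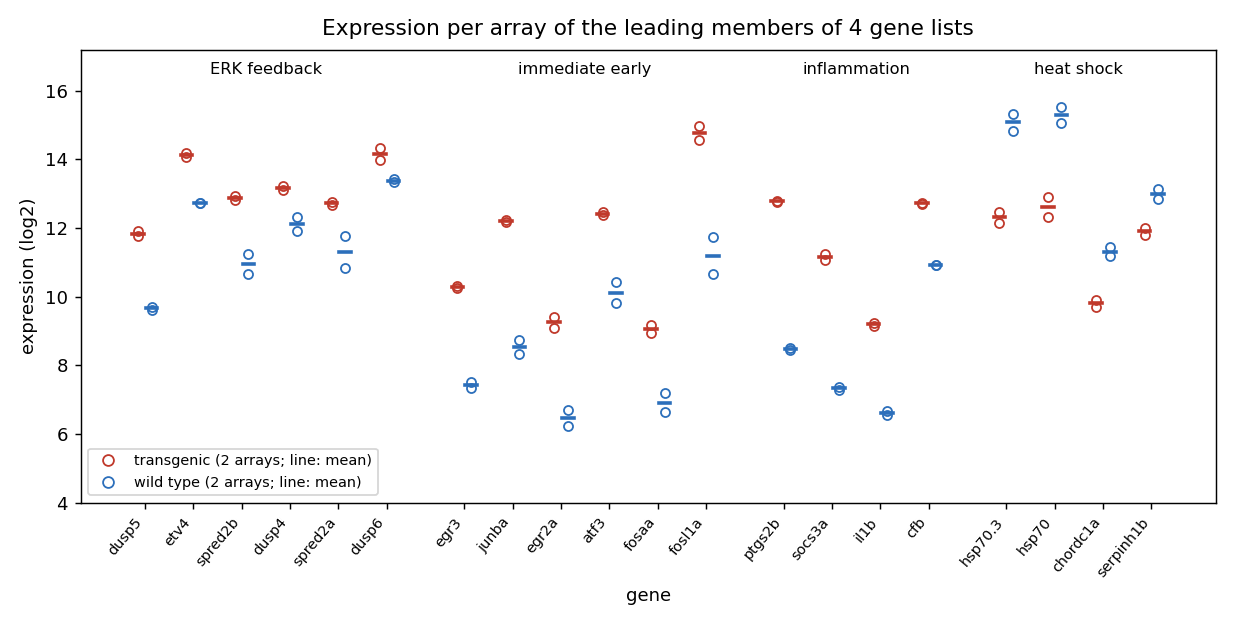
Log2 expression in each array of the leading members of the ERK feedback, immediate early, inflammation and heat shock lists, with red circles for the 2 transgenic arrays, blue circles for the 2 wild-type arrays and a line at each mean. Both red circles lie above both blue circles for genes such as dusp5 (rise of 2.17) and ptgs2b (4.31), and below them for hsp70.3 (-2.76) and chordc1a (-1.50).

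Inflammation genes rose in part. Of 30 measured, 11 rose, 0 fell and 19 did not pass, and the count was 11 adjusted over the list alone. Beside ptgs2b and socs3a, il1b, which encodes the cytokine interleukin-1 beta, rose by 2.58 ± 0.14, the complement factor B gene cfb by 1.81 ± 0.14, and cebpb, a transcription factor gene of the acute phase response, by 1.67 ± 0.14. The list shifted upward (camera adjusted p = 0.0407; adjusted p = 0.792 with an estimated correlation), although its median was only 0.07 and turned to -0.01 under quantile normalization and -0.02 under median centring, against a mean of 0.70. The call ended with the replicate number as a block (camera adjusted p = 0.0525) and without wild-type replicate 2. Leukocyte markers did not shift (camera adjusted p = 0.825): of 17 measured, il1b, the macrophage and pigment cell receptor gene csf1ra (1.74 ± 0.14) and cyba, an NADPH oxidase subunit gene (1.53 ± 0.30), rose and 0 fell, and the count was 3 adjusted over the list alone. The macrophage gene mpeg1.1 differed by -0.50 ± 0.20 (adjusted p = 0.14).

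Of 15 matrix remodelling genes measured, 4 rose and 1 fell. Next to mmp9, the rises included adam8a, a membrane metalloprotease gene (1.67 ± 0.14), and fn1b, a fibronectin gene (1.60 ± 0.14), and mmp11a fell by 1.26 ± 0.14. The counts were 5 higher and 2 lower adjusted over the list alone, and the list did not shift (camera adjusted p = 0.787). Endothelial genes included 5 risen, 0 fallen and 17 not passed among 22. They were led by the receptor genes flt4 (1.53 ± 0.19) and flt1 (1.42 ± 0.20), the secreted factor gene egfl7 (1.27 ± 0.20) and the tight junction gene cldn5b (1.25 ± 0.15), and 6 rose adjusted over the list alone. The endothelial list had a median of 0.23 (camera adjusted p = 0.0499; adjusted p = 0.792 with an estimated correlation), a call that ended under quantile normalization (adjusted p = 0.0649) and median centring (adjusted p = 0.0586).

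Heat shock genes fell in part. Of 24 heat shock protein and cochaperone genes measured, 0 rose, 11 fell and 13 did not pass; adjusted over the list alone, 13 fell. After hsp70.3 and hsp70, the falls with the smallest p were in chordc1a, an HSP90 cochaperone gene (-1.50 ± 0.18), and serpinh1b, a collagen chaperone gene (-1.09 ± 0.18), both of whose features fell. In the wild-type arrays hsp70.3 stood at 15.08 (SD 0.341, n = 2) and in the transgenic arrays at 12.31 (SD 0.238). The list shifted downward with a median of -0.67 (camera adjusted p = 0.00195; adjusted p = 0.792 with an estimated correlation).

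Other stress genes went both ways. In the unfolded protein and integrated stress response list, 5 of 24 rose and 5 fell (camera adjusted p = 0.812). The rises included sesn2 (1.42 ± 0.16) and chac1 (1.06 ± 0.15), which are induced by the integrated stress response, and hsp90b1, a chaperone gene of the endoplasmic reticulum, fell by 1.86 ± 0.23 (3.64-fold). Among 22 oxidative stress genes 1 rose and 3 fell, among them the metallothionein gene mt2 (-1.69 ± 0.15) and nqo1, a quinone reductase gene (-1.42 ± 0.15, 2 of 3 features past the threshold), without a shift of the list (camera adjusted p = 0.34). Of 14 p53 targets, the death receptor gene tnfrsf1a rose by 1.76 ± 0.14, while cdkn1a, which encodes the cell cycle inhibitor p21, and the stress gene sesn1 fell (-1.48 ± 0.30 and -1.07 ± 0.16; camera adjusted p = 0.944). Of 31 apoptosis genes, 2 rose and 3 fell, led by caspb, an inflammatory caspase gene that fell by 2.23 ± 0.16 (camera adjusted p = 0.944; the mean and median were above 0, and fry gave the list a downward direction). Adjusted over the list alone, 7 unfolded protein genes were higher and 5 lower, 1 oxidative stress gene was higher and 3 lower, 1 p53 target was higher and 2 lower, and 2 apoptosis genes were higher and 3 lower.

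Cell cycle genes gave few calls. Replication and S phase genes shifted downward as a set, with a median of -0.22 (camera adjusted p = 0.0499; adjusted p = 0.792 with an estimated correlation), a call that ended under quantile normalization (adjusted p = 0.078) and median centring (adjusted p = 0.0584). Of the 29 measured, 0 rose and the DNA polymerase delta subunit gene pold2 fell by 0.78 ± 0.15 (1 of 2 features past the threshold), and 0 passed adjusted over the list alone. The brighter feature of ccne1, a cyclin gene, differed by 0.58 ± 0.14 without passing, whereas its other feature passed upward (0.68). Of 22 mitosis genes, 0 rose and 0 fell, and 0 passed adjusted over the list alone (camera adjusted p = 0.567); the cyclin gene ccnb1 differed by -0.45 ± 0.14 (adjusted p = 0.086), with its 2 features of opposite sign. Among 8 genes of arrest and senescence, mmp9 and the IGF-binding protein gene igfbp1a (2.03 ± 0.14) rose, and cdkn1a and igfbp5a (-1.32 ± 0.19) fell, a count of 4 that also held adjusted over the list alone; the list had a median of -0.04, a mean of 0.43 and no shift (camera adjusted p = 0.812).

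Markers of muscle, heart and blood gave few calls. In skeletal muscle, tcap, which encodes a titin-binding protein of the sarcomere, rose by 3.09 ± 0.15 (8.49-fold) and myhz2, a fast myosin gene, by 0.94 ± 0.18, whereas the titin gene ttnb (-1.60 ± 0.14) and unc45b, a myosin chaperone gene (-1.02 ± 0.15), fell. Over the 40 muscle genes 2 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.543), and only 2 of the 6 features of ttnb passed. Of 16 heart muscle genes 0 rose and gjd6, a connexin gene, fell by 1.24 ± 0.22, also adjusted over the list alone (camera adjusted p = 0.812). Of 21 erythroid genes 0 rose, and the globin genes hbae5 (-2.0 ± 0.24) and hbaa1 (-1.49 ± 0.27), which have near-identical copies, fell, a count of 2 also adjusted over the list alone (camera adjusted p = 0.627).

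Nervous system, eye and pigment genes also held some of the calls. Of 44 neuronal genes 6 rose and 3 fell, among them scg2b, a secretory granule protein gene (1.32 ± 0.18), gad2, a GABA synthesis gene (1.04 ± 0.13), and p2rx3a, a purinergic receptor gene of sensory neurons (-1.39 ± 0.14), without a shift (camera adjusted p = 0.279). Of 37 neural progenitor genes 2 rose and 3 fell, such as the proneural gene ascl1b (-1.41 ± 0.14) and the forebrain gene emx3 (1.01 ± 0.15; camera adjusted p = 0.361). In the lens list foxe3, a lens transcription factor gene, fell by 1.55 ± 0.16 and pitx3 also fell (-0.68 ± 0.14), in a count of 1 higher, which ended under quantile normalization, and 4 lower of 29 (camera adjusted p = 0.787). Pigment and neural crest genes had csf1ra higher and 4 of 23 lower, including trpm1a (-1.15 ± 0.18) and mitfa, the master factor gene of melanocytes (-0.75 ± 0.14, 1 of 2 features past the threshold; camera adjusted p = 0.115). Adjusted over the list alone, 11 neuronal genes were higher and 3 lower, 2 neural progenitor genes were higher and 3 lower, 1 lens gene was higher and 4 lower, and 1 pigment or crest gene was higher and 5 lower.

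In the remaining tissue lists, 2 of 39 epidermal genes rose and 2 fell, including the E-cadherin gene cdh1 (1.34 ± 0.14) and krt15 (-1.10 ± 0.19; camera adjusted p = 0.812). Of 21 notochord and hatching gland genes 2 rose and 2 fell, including the collagen gene col11a2 (1.53 ± 0.23) and the caveolin gene cav1 (-1.04 ± 0.15, 1 of 2 features past the threshold; camera adjusted p = 0.825). Of 28 endoderm, liver and yolk genes 0 rose, and ahsg2 (-1.15 ± 0.17) and the trypsin gene prss1 (-0.81 ± 0.14) fell (camera adjusted p = 0.136). Adjusted over the list alone, these lists held 2 higher and 2 lower, 4 higher and 3 lower, and 0 higher and 2 lower.

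Targets of 5 other developmental pathways did not shift as sets. Of 13 Wnt targets, cdx4 (0.85 ± 0.18) and tbx6 (0.65 ± 0.14) rose and 0 fell, calls that ended under both other scalings, where 0 passed (camera adjusted p = 0.825); the 2 features of tbx6 differed in sign. Among 14 Notch targets hey1 rose by 1.13 ± 0.22 and her12 fell by 0.82 ± 0.18 (camera adjusted p = 0.812). Among 17 Hedgehog targets prdm1a rose by 0.92 ± 0.15 and foxf2a fell by 0.95 ± 0.14 (camera adjusted p = 0.812). Of 16 BMP and TGF-beta targets 1 rose, msx2a (1.34 ± 0.15), and 3 fell, including msx3 (-0.89 ± 0.15; camera adjusted p = 0.825). Of 20 retinoic acid genes 1 rose, a call that ended under both other scalings, and 3 fell, including cyp26a1, which encodes a retinoic acid degrading enzyme (-1.07 ± 0.14), and hoxb1a (-0.66 ± 0.15; camera adjusted p = 0.141). Adjusted over the list alone, the counts were 2 higher and 0 lower for Wnt, 2 and 2 for Notch, 1 and 1 for Hedgehog, 1 and 3 for BMP and TGF-beta, and 1 and 5 for retinoic acid.

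Metabolic and translation genes gave few calls too. Of 24 glycolysis genes 1 rose, a call that ended under median centring, and 2 fell, including gpib (-0.82 ± 0.15; camera adjusted p = 0.543). Of 33 ribosome biogenesis genes mybbp1a rose by 0.86 ± 0.17 (1 of 2 features past the threshold) and 0 fell (camera adjusted p = 0.881). Of 47 ribosomal protein genes 0 rose and rpsa fell by 1.02 ± 0.15 (camera adjusted p = 0.141). In these 3 lists 0 genes passed adjusted over the list alone. Of 24 clock genes per1b rose by 1.39 ± 0.25 and tefa fell by 0.99 ± 0.15, the same count as adjusted over the list alone (camera adjusted p = 0.812).

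Of the 35 lists, 6 passed camera at an adjusted p of 0.05, 4 upward and 2 downward, and 0 passed with an estimated correlation. That setting also called 0 of 50 simulated shifted lists, so the lack of a call with it cannot decide against a list. The fry test, which asks whether the genes of a list move on balance in the same direction, gave an adjusted p of 0.0497 for inflammation and 0.0503 for immediate early genes, 0.0506 for ERK feedback and 0.0572 for heat shock. Lists that camera did not call had like values in fry: 0.0503 for senescence and arrest, retinoic acid and oxidative stress, and 0.0506 for growth factors and neural progenitors. Median, mean and test differed in sign for lists without a call. The median was below 0 with a mean above 0 and an upward direction for senescence and arrest, matrix remodelling, leukocyte markers and Wnt targets. It was above 0 with a mean below 0 and a downward direction for erythroid and Hedgehog genes. For epidermis the mean was 0.02 with a median of -0.10 and a downward direction.

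**Figure D3:**
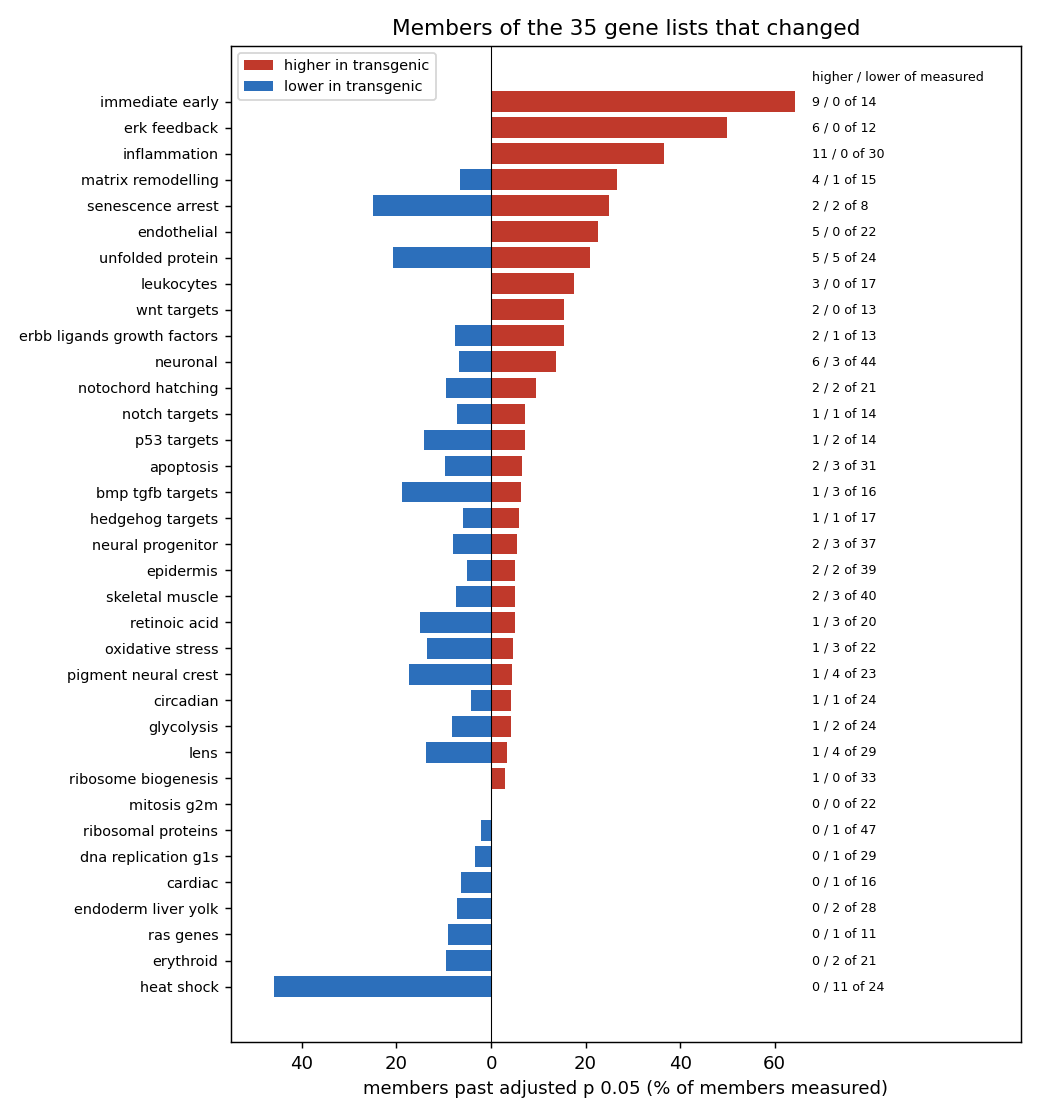
Share of the measured members of each of the 35 gene lists that passed an adjusted p of 0.05 (limma, over all features), with red bars for members higher and blue bars for members lower in the transgenic embryos and the counts at the right. Immediate early genes (9 of 14 higher) stand at the top and heat shock genes (11 of 24 lower) at the bottom.

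The share of higher calls moved with the scaling: 58.6% of the 6538 passing features were higher as deposited, against 49.7% of 6843 after quantile normalization and 47.7% of 6946 after median centring. The transgenic values of 25116 features (67.6%) lay on the same side of both wild-type values, where chance gives 33.3%. In the authors' deposited table, 25150 features had a q-value under 0.05, 12981 higher and 12169 lower, and 4587 of them had a fold change of at least 2. All 6538 features called by limma were among the 25150. Without either transgenic array, limma called 0 features after adjustment, with 7482 (replicate 1 left out) and 7548 (replicate 2 left out) under an unadjusted p of 0.05. Without wild-type replicate 2, 12163 were called.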

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

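The alternatives were fixed before the data were examined, apart from the lists extended through human ortholog names, which were chosen after seeing the data. Of 119 named genes past the threshold, 0 changed sign under any alternative, and 14 lost the call under an alternative that kept all arrays. Among the 119, 76 were measured in every alternative, of which 67 stayed past the threshold in all that kept all arrays. The other 43 were left out by a filter on dim features. The gene hrasb, never called, turned from 0.08 to -0.01 under median centring. The 6538 features past the threshold became 11247 at an adjusted p under 0.10, 25150 by the authors' deposited q-values (a test that is not given) and 2547 when genes with a symbol were counted, and stood between 5320 and 9291 under the other settings with all arrays. The 3809 at 2-fold became 1235 with the features below the median level left out and 2464 with log2(value + 50), both of which remove or shrink changes of dim features, and 1426 as genes with a symbol. Leaving out each array gave 0 to 12163 features and 0 to 5693 at 2-fold in limma: 0 without either transgenic array, where the smallest adjusted p was 0.0719 or 0.0698, and 12163 without wild-type replicate 2. Without a transgenic array the spread comes from the wild-type pair alone, whose arrays differed more (SD of the difference 0.457, transgenic pair 0.278). The 6 lists became 0 with an estimated correlation and 1 with fry, and the extended lists gave 5. The estimated correlation also called 0 of 50 simulated shifts, but of independent features. The simulation therefore cannot show whether the preset 0.01 is too low for lists such as heat shock (estimated correlation 0.112) and immediate early genes (0.111). For replication genes the estimated correlation was -0.004, below the preset, yet the camera adjusted p still went from 0.0499 to 0.792. A high correlation was therefore not what ended that call. With the preset correlation the highest adjusted p over the alternatives was 0.00998 for immediate early, 0.0113 for heat shock and 0.0142 for ERK feedback genes. It was 0.0941 for inflammation (without wild-type replicate 2; call lost in 2 alternatives), 0.181 for replication (without wild-type replicate 1; lost in 8) and 0.15 for endothelial genes (without wild-type replicate 1; lost in 9). The replicate numbers are only shared numbers, with a correlation of 0.206 between the replicate differences; with the replicate block 7291 features and 3 lists passed, inflammation, replication and endothelial genes each having an adjusted p of 0.0525. Signal over background was not given, which limits what can be said of dim features.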

Other observations

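Many features without a zebrafish symbol had a human ortholog name in the authors' deposited table, and reading the lists through those names, a step chosen after seeing the data, added members to the ERK feedback and immediate early groups. The 6 added ERK feedback features all rose in limma: the orthologs of the Sprouty genes SPRY4 (1.89 ± 0.14, log2 fold change ± SE, n = 2 arrays per genotype), SPRY1 (1.85 ± 0.24) and SPRY2 (1.37 ± 0.15), of DUSP2 (1.76 ± 0.14), of ERRFI1, an inhibitor of the EGF receptor (1.64 ± 0.14), and of IL17RD (0.75 ± 0.17). The extended list then held 12 risen and 0 fallen of 18. Among 20 immediate early members 13 rose, now with features named after EGR1 (2.96 ± 0.22), IER2 (2.87 ± 0.14) and FOSL2 (2.69 ± 0.16). The ortholog of NR4A1, a nuclear receptor gene, went the other way and fell by 2.60 ± 0.21. The ortholog of HBEGF, an EGF receptor ligand, rose by 2.12 ± 0.15 and that of IRF1, an interferon response factor, by 2.46 ± 0.22, from a wild-type level so low that the size is uncertain. Other features with these names did not always pass: 3 of 7 for SPRY2, 2 of 3 for HBEGF and 1 of 4 for EGR1 did not. An ortholog name cannot tell zebrafish paralogs apart. The gene egr3, already in the immediate early list, also carries the name EGR1, so an added member need not be a further gene.

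Among the features with an ortholog name but no symbol, the ortholog of the collagenase gene MMP13 rose by 5.18 ± 0.14, from 8.25 and 8.36 in the wild-type arrays to 13.48 in both transgenic arrays. The other feature with that name, mmp13b, differed by -0.12 without passing. Both features named after the integrin gene ITGA2 rose (2.26 and 4.38). The kinase name PIM3 is shared by 135 features, of which 90 rose, 1 fell and 44 did not pass, with log2 fold changes from -0.62 to 4.28. Of 8 features named after the protease inhibitor gene TIMP2, 5 rose and 3 did not pass (-0.06 to 3.85). The largest rises of ITGA2 (from 4.73 and 5.20 in the wild-type arrays), PIM3 (from 5.76 and 4.13) and TIMP2 (from 5.25 and 4.04) start where an unknown share of the signal is background, so their size is uncertain, as is that of the NOS1 fall. Of 2 features named after NOS1, the neuronal nitric oxide synthase, a feature with low transgenic values (5.17 and 4.05) fell (-4.64 ± 0.38) and the other feature did not pass (-0.71 ± 0.28, adjusted p = 0.14). Of 12 HSPA8 features 8 fell, 0 rose and 4 did not pass (-4.05 to 0.13), and of 6 HSPA4 features 5 fell and 1 did not pass (-4.02 to -0.16). These counts include features with a symbol: hsp70.3 and hsp70, reported above, carry the name HSPA8. The zebrafish gene hspa8 itself differed by only -0.08 ± 0.15 (limma adjusted p = 0.74).

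The tests below were chosen after the result was seen, except for that of signal shared between the copies of gene families, which was chosen before its value was seen. The bounds of the scaling test were set when its counts were known, and those of the floor test when the median change over all features was known; its dimmer band was added once the value of the middle band had been seen.

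Of 24 heat shock genes, 11 were lower in the transgenic embryos, 0 higher and 13 not past the threshold (camera adjusted p = 0.00195; 0.792 with an estimated correlation), although both genotypes had been heat shocked. Signal shared among the copies of HSP70 as the whole cause is argued against by the other members of the list: the 18 members outside the HSP70 family had a median of -0.59, and 8 of them fell and 0 rose, next to 3 falls among 6 HSP70 members. A heat shock that differed between the pools of each genotype cannot be told apart from an effect of the genotype: 18 of the 24 members were lower in the transgenic arrays, as either would give, and each pool had a single genotype. An effect of the transgene on the decline of the heat shock response is an open biological explanation and was not tested.

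Of 30 inflammation genes, 11 were higher in the transgenic embryos, 0 lower and 19 not past the threshold (camera adjusted p = 0.0407; 0.792 with an estimated correlation). More leukocytes in the transgenic pools as the whole cause would raise leukocyte markers as a set. This is argued against by 24 markers outside the inflammation list, found by symbol or human ortholog name, whose median was -0.03 (median absolute deviation 0.42). The 11 called inflammation genes had a median of 1.67, but they were chosen for rising, so the gap between these medians is partly built in. The median of all 30 was 0.07. The abundant neutrophil gene npsn stood at 12.42 in the transgenic and 12.12 in the wild-type arrays (limma adjusted p = 0.33), and rac2 at 11.93 and 11.65 (adjusted p = 0.19). However, 4 of the 24 rose, including the MPO (0.78 ± 0.16) and LCP1 (0.68 ± 0.15) orthologs, so a smaller rise stays open. Neutrophil, macrophage and pan-leukocyte genes are mixed among the 24, so their median cannot argue against more cells of a single type, such as neutrophils. The LYZ ortholog differed by 0.63 ± 0.18 (limma adjusted p = 0.07) and the macrophage gene mpeg1.1 by -0.50 ± 0.20 (adjusted p = 0.14). Of the 17 leukocyte genes with a symbol, 3 are also in another list. The calls changed little with the scaling: at least 10 members were called higher under each of the other 2 scalings, against 11 as deposited. However, the median change over all features moved only from 0.007 to -0.049 under quantile normalization and -0.086 under median centring. Calls with a median of 1.67 could hardly be lost by such shifts, so their count cannot decide about scaling. The median of the list turned below 0 under both. Expression of these genes in other cells of the transgenic embryos may account for the rise of these 11, as a hypothesis that was not tested.

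Genes raised at least 2-fold lay next to each other more often than chance gives: among 11256 genes in genome order there were 83 neighbouring raised pairs, against a mean of 25 in 10000 shuffles (permutation p = 1e-04, the smallest they can give). Lowered genes did so too, with 23 pairs against a mean of 13.6 (permutation p = 0.0096). Families of like-named neighbours held part of the neighbouring raised pairs, such as the trace amine receptor genes (21 of 28 taar genes higher, 0 lower, with medians of 4.34 in the wild-type and 5.85 in the transgenic arrays, so low that background has an unknown share) and clustered protocadherin genes (18 of 39 pcdh genes higher, 0 lower). Pairs counted as like-named had the same ortholog name or the same opening characters in their symbols. That rule also removes neighbours with clone names opening with si:, which need not be related. Without such pairs 30 raised pairs were left, against a shuffled mean of 23.2 and 95th percentile of 31 (permutation p = 0.091). For lowered genes 18 pairs were left, against a mean of 12.6 and 95th percentile of 18 (permutation p = 0.084). Because of the clone names, this cannot decide whether families account for the neighbouring pairs, and the taar and pcdh families hold 0 lowered genes. A higher floor on the transgenic arrays as the cause is argued against, since all features as bright as the middle 38 of the 78 genes in like-named raised pairs had a median change of 0.03, and those as bright as the dimmest 20 a median of 0.06. Signal shared between copies cannot be told apart from joint regulation of whole families. The partners of a like-named pair differed in wild-type level by a median of 0.82, against 2.11 for random pairs of raised genes (ratio 0.39). This met the bound set for shared signal before the value was seen. However, levels of different probes depend on their affinity and related genes can have like levels, so meeting that bound decides nothing.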
